A study of Mus musculus with 58 samples.

How the data were processed

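RNA was measured in 28 libraries of mouse origin, in groups of 2. Poly(A) RNA was sequenced from epididymal white adipose tissue (eWAT) and inguinal white adipose tissue (iWAT) of Hira f/f mice (controls) and Hira f/f;Adipoq-Cre mice (KO). One set of mice ate chow and was 23 weeks old, and the other ate a high-fat diet (HFD) for 8 weeks and was 16 weeks old. Poly(A) RNA was also sequenced from 3T3-L1 cells, a mouse preadipocyte line, on day 0 and day 4 of differentiation. New RNA labelled with 5-ethynyl uridine (EU-RNA) and depleted of ribosomal RNA was sequenced on day 4 from 3T3-L1 cells that lack Hira and carry human HIRA fused to a dTAG degron. These cells received DMSO for the control groups or the degrader dTAG13 for 3, 6 or 24 h. Differentiation, per the labels, began with 2 days of dexamethasone (1 µM), IBMX (0.5 mM) and insulin (10 µg/mL). Values for the 30 chromatin immunoprecipitation and input samples of the series were not among the tables used, so no chromatin result is given.

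The deposited tables give read counts and RPKM (reads per kilobase per M) per RefSeq transcript. The authors counted reads over exons for tissue and over whole gene bodies, introns included, for EU-RNA, per the file names. The build was mm9 per the labels, which name bcl2fastq, Bowtie2, STAR and SICER (versions 1.1 and 2) for the whole series without saying which step used which. STAR appears in the names of the HFD and EU-RNA tables only, so an aligner difference between chow and HFD libraries cannot be ruled out from the labels. The counting program and the strand setting are not stated in the tables or labels used. The deposited counts were whole numbers and entered all tests. The deposited RPKM values served only for checks of the counts and of the share of reads in exons.

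The 29082 transcripts were reduced to 22835 genes by keeping, for each of the 3906 genes with more than 1 transcript, the transcript with the highest total over the libraries of a set, because transcripts of 1 gene share reads. Of these genes, 22702 had their Entrez identifier in the reference gene table, which was used for names, older symbols and gene order and is of a later build than mm9. Genes are named by the symbols in the tables. Totals over genes ran from 11.4 to 34.3 M reads in tissue, from 110.9 to 118.6 M in 3T3-L1 mRNA and from 77.2 to 107.6 M in EU-RNA. Here M stands for mega. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. No 2 replicates of a group held identical counts.

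Tests used edgeR 4.0.16 in R 4.3.3. Each set (tissue, 3T3-L1 mRNA, EU-RNA) had its own model with 1 coefficient per group. Low counts were removed with filterByExpr, libraries were scaled with TMM, and quasi-likelihood F tests were run with a robust fit. Adjusted p is Benjamini-Hochberg over the genes tested, 18077 in tissue, 14373 in 3T3-L1 mRNA and 17868 in EU-RNA, and a gene was called under 0.05. The spread is pooled over the groups of a set, with 8, 2 and 4 residual degrees of freedom. The common biological coefficient of variation was 37.3% in tissue, 2.83% in 3T3-L1 mRNA and 10.4% in EU-RNA. The labels do not say that replicates are separate animals or separate cultures, so p-values measure the spread between these samples. SE of a log2 fold change is its size over the root of F. Levels are counts per M on TMM-scaled library sizes (CPM), given as mean ± SD with n = 2 per group. All 16 comparisons were fixed with their tests, gene lists and alternatives before the data were examined, except where a later choice is stated.

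In all, 29 gene lists (cell types, lipid and energy metabolism, chromatin and transcription, stress and signalling) were fixed in the same way. The sex-linked list served only to check the libraries. The Y-linked gene Ddx3y measured 62.9 to 142 CPM in tissue and 34.9 to 50.7 CPM in EU-RNA, but 0 in each 3T3-L1 mRNA library, and Xist stayed under 1 CPM in all sets. The others were tested with camera (limma 3.58.1, preset correlation 0.01) where at least 5 members were tested, with Benjamini-Hochberg over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Calls of members are given over all genes tested and adjusted over the list alone. Lists of the 200 genes most induced and the 200 most repressed on day 4 were tested in the other sets. Genes are named by a fixed rule. It takes Hira and Adipoq always. It takes the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between the libraries. It also takes up to 4 called members from each of up to 6 lists that passed camera or held at least 3 called members, or 2 uncalled members where a passing list had no call. Genes outside the rule were chosen after their values were seen, and the text says so.

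The model was tested on simulated data, a check written after the results were seen. Fold changes of 1.5, 2 and 4 were put into 200 genes with the dispersions of each set. A 2-fold change was called in 6.1% of such genes for KO in eWAT on chow, 61.2% for the KO effect averaged over 4 settings, 95.5% for day 4 and 71.9% for EU-RNA at 24 h. A 4-fold change was called in 47.7%, 83.1%, 98.5% and 96.9%. In the simulated lists, all 16 changed lists were found and 1 unchanged list was called. Genes were drawn independently of one another, so this does not measure false calls of lists whose genes are correlated.

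The alternatives set in advance were RLE scaling, no filter on low counts, DESeq2 1.42.0, a model with only the libraries compared (limma-voom for the average), replicate number as a block, leaving out each library in turn, and changed settings of the list and overlap tests. Alternatives chosen after the data were seen were the mean over transcripts, subtraction of a background rate measured in silent receptor genes, models without the HFD KO libraries or the 6 h EU-RNA libraries, a block with crossed replicate numbers in eWAT, and separate chow control libraries for the overlap of KO and diet in eWAT. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.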

Results

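The series measured RNA in mouse adipose tissue lacking the histone H3.3 chaperone HIRA in adipocytes and in 3T3-L1 adipocytes whose HIRA can be degraded. Its title states the interest in adiponectin expression, adipose expansion in obesity and release of paused RNA polymerase II. Adipose tissue gave 16 libraries, 2 for each combination of depot, diet and genotype. On chow, eWAT control libraries held 29.9 and 33.7 M reads over genes, eWAT KO 25.2 and 32.9, iWAT control 30.1 and 27.0, and iWAT KO 23.2 and 25.5. On HFD, eWAT control libraries held 22.7 and 34.3 M, eWAT KO 16.7 and 16.7, iWAT control 20.1 and 20.9, and iWAT KO 11.4 and 17.4. The 3T3-L1 mRNA libraries held 111.3 and 111.4 M reads on day 0 and 110.9 and 118.6 M on day 4. The EU-RNA libraries held 87.0 and 85.9 M with DMSO, 82.7 and 77.2 M at 3 h of dTAG13, 91.3 and 78.3 M at 6 h, and 107.6 and 88.7 M at 24 h.

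Hira, the targeted gene, had lower mean levels in KO than in control tissue in each of the 4 settings. In eWAT on chow it measured 19.8 ± 0.38 CPM in KO against 31.6 ± 1.78 in controls, and in iWAT on chow 30.2 ± 7.41 against 36.3 ± 5.43. On HFD it measured 19.8 ± 0.848 against 28.7 ± 2.62 in eWAT and 18.8 ± 0.168 against 37.1 ± 2.7 in iWAT. The change was called in iWAT on HFD (log2 fold change −0.98, SE 0.18, adjusted p 0.0312) but not in eWAT on chow (−0.68, adjusted p 0.147), eWAT on HFD (−0.54, adjusted p 0.158) or iWAT on chow (−0.27, adjusted p 0.926). Averaged over the settings Hira fell by 0.61 on the log2 scale (SE 0.09, adjusted p 0.00227). The counts cover all exons of the gene, and the tissue holds other cells beside adipocytes. Adipoq, which encodes the adipocyte hormone adiponectin and whose regulatory sequence drives the Cre transgene, fell by 1.18 in eWAT on chow (adjusted p 0.0381) and by 1.60 in iWAT on HFD (adjusted p 0.0128). Its log2 fold changes of −1.38 in iWAT on chow (adjusted p 0.0508) and −0.92 in eWAT on HFD (adjusted p 0.0761) did not pass. Averaged over the settings Adipoq fell by 1.27 (SE 0.12, adjusted p 1.33e-04).

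**Figure D1:**
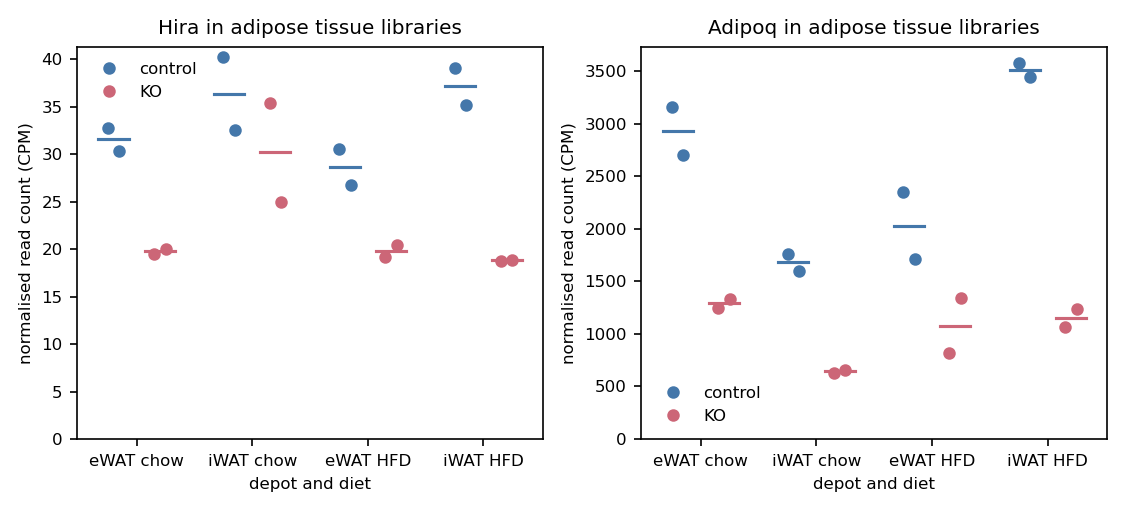
Normalised read counts (CPM) of Hira and Adipoq in each adipose tissue library, by depot and diet. Points are libraries and bars are means of 2, with controls in blue and KO in red. For Adipoq both KO points lie under both control points in every setting. For Hira the iWAT chow KO points, with a mean of 30.2, overlap the controls, with a mean of 36.3. There KO replicate 1 measured 35.4, above control replicate 2 at 32.5.

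The first comparison asked what KO changed in eWAT on chow. Macrophage genes were the group that rose most clearly. Of the 25 tested, 12 rose and none fell, 22 rose and 1 fell adjusted over the list alone, and the median log2 fold change was 1.49 (camera adjusted p 1.46e-66, and adjusted p = 0.00819 with an estimated correlation). Gpnmb, a glycoprotein of lipid-laden macrophages, rose from 30.4 ± 1.95 to 492 ± 92.3 CPM (log2 fold change 4.02, SE 0.20, adjusted p 3.53e-06). The lysosomal protease gene Ctss rose by 2.09 and so did Lgals3, the galectin-3 gene (both with adjusted p 9.77e-04), and the immune adaptor gene Tyrobp rose by 1.59 (adjusted p 0.00202). Among the largest rises were Clec4d, a C-type lectin receptor of myeloid cells (4.35, adjusted p 0.0027), the macrophage elastase gene Mmp12 (3.53, adjusted p 0.0353), S100b, a calcium-binding protein known from glia (3.89, adjusted p 0.00403), Tph2, a serotonin synthesis enzyme (4.43, adjusted p 0.0262), and the proton channel gene Otop1 (3.79, adjusted p 0.00202).

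Adipocyte genes moved down in eWAT on chow. Of 25 tested members of the adipocyte identity list 3 fell, 6 adjusted over the list alone, with a median of −0.42 (camera adjusted p 5.44e-07, but adjusted p = 0.374 with an estimated correlation). They were Adipoq, Retn, the resistin gene (−1.76, adjusted p 0.0158), and Adrb3, the β3-adrenergic receptor gene (−1.41, adjusted p 0.0498). Other large falls were Klf14, a transcription factor (−3.38, adjusted p 0.00672), Ifi27l2a, an interferon-inducible gene (−2.94, adjusted p 0.0179), Bche, the butyrylcholinesterase gene (−1.64, adjusted p 0.0376), and the Ras-related genes Rasl11b (−1.75) and Rasgrf2 (−1.52). No lipogenesis gene was called among 22, and 5 fell adjusted over the list alone (median −0.42, adjusted p = 0.374 with an estimated correlation), with Thrsp at −0.85 (adjusted p 0.0631) and Slc25a1 at −1.14 (adjusted p 0.103). Matrix, cell cycle and immediate early lists had medians of 0.50, 0.51 and 0.38, each with adjusted p = 0.158 with an estimated correlation. Their called members were Timp1, a protease inhibitor (1.84, adjusted p 0.00805), and Atf3, a stress-induced transcription factor (2.28, adjusted p 0.00652). The cell cycle genes Tk1 (1.37, adjusted p 0.0601) and Cdk1 (1.33, adjusted p 0.117) did not pass.

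In edgeR 163 of 18077 genes were called in eWAT on chow, 145 up and 18 down. The share of rises was smaller with DESeq2 (424 up and 188 down) and with the 4 libraries alone (400 up and 121 down). Leaving out control replicate 1 or 2, or KO replicate 1 or 2, left 4, 36, 51 and 49 genes, a replicate block left 13, and DESeq2 called 612, and of the 19 called genes named here Gpnmb alone stayed called whichever library was left out. Epididymal genes summed to 1390 CPM in control replicate 2 and to at most 24 in the other 3 libraries, so genes of that tissue differ within the groups.

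In iWAT on chow, where the same question was asked, 10 genes rose and 20 fell. S100b rose from 7.9 ± 1.51 to 82.2 ± 21.2 CPM (3.38, SE 0.47, adjusted p 0.046). Also higher were Plekhg6 (2.56, adjusted p 0.0376), the carbohydrate sulfotransferase gene Chst8 (2.31), the mitochondrial protein gene Chchd10 (2.14), the pantetheinase gene Vnn1 (1.91) and the kinase gene Dmpk (1.73), each with adjusted p 0.046. The falls with the same adjusted p included Ripk4 (−3.44), Ifi27l2a (−3.32), Lrrc4 (−2.91), the cadherin gene Celsr2 (−2.72), the cannabinoid receptor gene Cnr1 (−2.44) and the cytokine gene Ctf1 (−2.13). Of the adipocyte identity list 2 of 25 genes fell, 6 adjusted over the list alone (median −0.41, adjusted p = 0.409 with an estimated correlation): Adrb3 (−2.06) and Retn (−1.81). Pik3cb, a catalytic subunit gene of phosphoinositide 3-kinase, fell by 1.07 as the 1 called member of 16 in the insulin signalling list, and 1 fell adjusted over the list alone (median −0.36, adjusted p = 0.532 with an estimated correlation).

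No member of the lipogenesis, matrix, immediate early or mammary epithelium lists was called in iWAT on chow, although these lists passed camera with the preset correlation. Adjusted over the list alone, 6 of 22 lipogenesis genes fell and none of the other lists was called. With an estimated correlation these lists had adjusted p = 0.409, 0.515, 0.296 and 0.296. Slc25a1 had a log2 fold change of −1.44 (adjusted p 0.0967), Me1 of −0.96 (adjusted p 0.169), Lox of 0.66, Timp1 of 0.83, Fosb of 3.14 and Cyr61 of 0.73. Of the keratin genes, Krt14 measured 28.7 CPM in control replicate 1 but 0.0695 in control replicate 2, beside 0.125 and 0 in KO, and Krt8 had −2.60, neither called, and the mammary list reached 117 CPM in 1 control library and 12.6 in the other. Skeletal muscle genes summed to 7170 CPM in control replicate 1, against 33400 in control replicate 2 and 26100 and 38700 in KO, so that control library held less muscle RNA than the other 3. Leaving out control replicate 1 or 2, or KO replicate 1 or 2, changed the count of 30 to 2, 3, 0 and 384. The block left 1 gene, the model without the HFD KO libraries 0, the 4 libraries alone 0 and no filter 18, while DESeq2 called 260. None of the 15 called genes named here stayed called whichever library was left out.

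In eWAT on HFD macrophage genes were lower in KO than in controls. Of 25 tested, 5 fell and none rose, 12 adjusted over the list alone, with a median of −0.68 (camera adjusted p 1.33e-10, but adjusted p = 0.235 with an estimated correlation). Gpnmb fell from 814 ± 148 to 212 ± 23.9 CPM (−1.94, SE 0.19, adjusted p 0.00237). Lgals3 fell by 1.18 (adjusted p 0.0229), the lysosomal glycoprotein gene Cd68 by 1.26 (adjusted p 0.025) and the integrin gene Itgax by 1.42 (adjusted p 0.0256). Itgad, an integrin gene outside the macrophage list, fell from 58.1 ± 7.32 to 1.94 ± 1.04 CPM (−4.89, adjusted p 7.07e-05). It did not follow that list across depots. In iWAT on HFD it fell too (−5.47), while summed macrophage genes were 3500 to 3620 CPM in KO and 2350 to 2500 in controls. Further falls in eWAT on HFD were Gpr50, an orphan receptor gene (2 counts in KO, 557-fold lower with a counting interval of 154 to 4600, adjusted p 0.0116), the lipase gene Lipf (2 counts in KO, 201-fold lower, interval 55.4 to 1660, adjusted p 0.0261), Klf14 (−3.24, adjusted p 0.0116), Kcne1l (−3.49, adjusted p 0.0496) and the lymphocyte receptor gene Cd6 (−3.40, adjusted p 0.0448).

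Of 20 genes of lipolysis and fatty acid oxidation 2 fell in eWAT on HFD, 5 adjusted over the list alone (median −0.48, adjusted p = 0.466 with an estimated correlation). They were Ehhadh, a peroxisomal oxidation enzyme (−1.68, adjusted p 0.0229), and Decr1, a mitochondrial one (−1.20, adjusted p 0.025). The largest rises were the hepatocyte growth factor-like gene Mst1 (5.71, adjusted p 0.0168), S100b (4.54, adjusted p 0.00531), the smooth muscle gene Cnn1 (3.54, adjusted p 0.0475), the neuronal splicing factor gene Rbfox3 (3.52, adjusted p 0.0496), the cytochrome P450 gene Cyp2f2 (3.38, adjusted p 0.0108) and the transcription factor gene Olig1 (3.3, adjusted p 0.034). S100b was the 1 called member of 10 in the neural and Schwann list, with 2 up adjusted over the list alone (median 0.80, adjusted p = 0.141 with an estimated correlation). Of 11 mesothelial genes the keratin gene Krt19 rose (1.99, adjusted p 0.0226), 5 adjusted over the list alone (median 1.29, adjusted p = 0.0832 with an estimated correlation). Mesothelial genes summed to 528 and 850 CPM in KO and to 228 and 267 in controls, and epididymal genes to 9470 and 814 CPM in KO and to 153 and 1140 in controls. Mammary list genes Krt8 (1.95, adjusted p 0.12) and Krt18 (2.23, adjusted p 0.134), which mesothelium also expresses, and cell cycle genes Ccne1 (−1.07, adjusted p 0.0982) and Mcm5 (−0.79, adjusted p 0.11) did not pass.

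The 4 HFD KO libraries had other marks of their own. Reads on 1450 olfactory and vomeronasal receptor genes, which adipose tissue should not express, made 54.9 to 87.8 per M in eWAT HFD KO and 147 to 192 per M in iWAT HFD KO, against 18.9 to 36.8 in the other 12 libraries. Their share of reads in exons was 56.1 to 79.3% of the highest library, against 89.9% or more elsewhere. Erythrocyte genes summed to 11600 and 20000 CPM in eWAT HFD KO, to 6570 and 17500 in iWAT HFD KO and to at most 8620 in the rest. After subtraction of the receptor gene rate, chosen after the data were seen, 107 of 111 genes higher in eWAT HFD KO and 187 of 205 lower genes were still called. In edgeR 316 genes were called in eWAT on HFD, 111 up and 205 down, but without KO replicate 1, the library with the most epididymal RNA, 31 were up and 12 down. Leaving out control replicate 1 or 2, or KO replicate 1 or 2, gave 36, 148, 43 and 1214 genes, the block left 1, the 4 libraries alone 0, and DESeq2 called 1472, with 45.2% up against 35.1% in edgeR. Of 19 called genes named here S100b, Gpr50, Itgad and Gpnmb stayed called whichever library was left out.

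**Figure D2:**
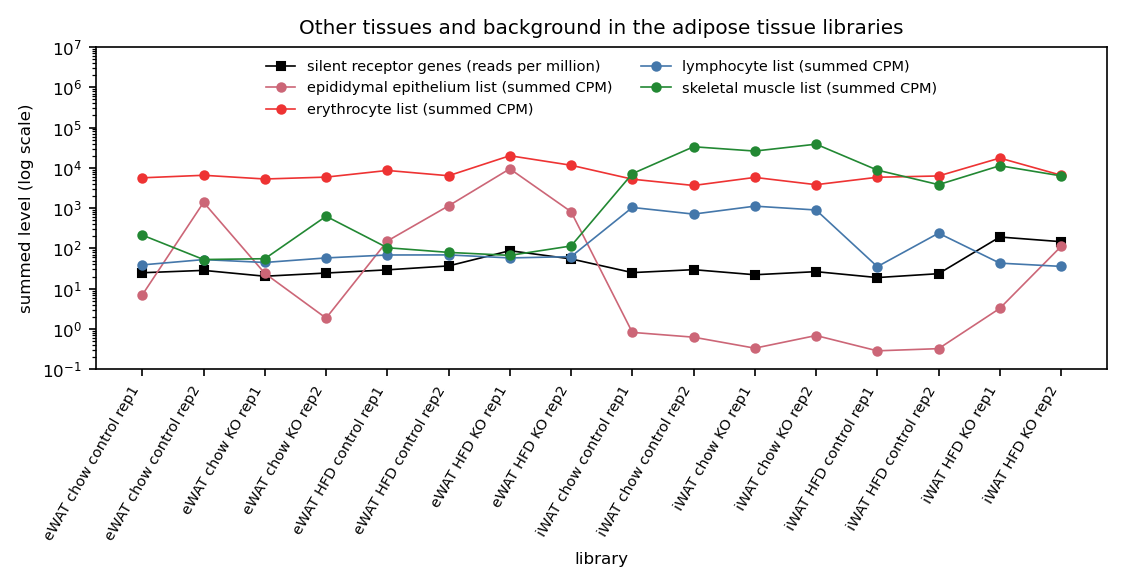
Summed levels in each adipose tissue library, on a log axis: reads per M on 1450 silent receptor genes (squares) and summed CPM of 4 fixed gene lists (circles), joined only to guide the eye. Epididymal genes reach 9470 CPM in 1 eWAT HFD KO library, and receptor genes reach 192 per M in 1 iWAT HFD KO library.

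In iWAT on HFD 92 genes rose and 103 fell. Adipocyte genes fell, 4 of 25 and 9 adjusted over the list alone, with a median of −0.43 (camera adjusted p 5.77e-10, but adjusted p = 0.426 with an estimated correlation). Beside Adipoq they were Retn (−1.82, adjusted p 0.0166), Adrb3 (−1.58, adjusted p 0.0316) and the lipid droplet gene Cidec, which went from 5400 ± 158 to 2450 ± 93.2 CPM (−1.14, adjusted p 0.0465). Lipogenesis genes fell too, 3 of 22 and 6 adjusted over the list alone (median −0.33, adjusted p = 0.426 with an estimated correlation). They were Slc25a1, the mitochondrial citrate carrier (−1.90, adjusted p 0.0128), Me1, malic enzyme (−1.36, adjusted p 0.014), and Insig1, a regulator of sterol synthesis (−1.58, adjusted p 0.0459). Of 20 lipolysis and oxidation genes Decr1 (−1.27, adjusted p 0.0238) and Ehhadh (−1.47, adjusted p 0.0405) fell, 3 adjusted over the list alone (median −0.46, adjusted p = 0.426 with an estimated correlation).

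Other falls in iWAT on HFD were Itgad, from 132 ± 13.2 to 2.97 ± 0.139 CPM (−5.47, SE 0.33, adjusted p 2.36e-05), Dnajc6, a clathrin uncoating factor (−3.76, adjusted p 9.23e-05), Prps1, a phosphoribosyl pyrophosphate synthetase (−2.77, adjusted p 0.00202), Ifi27l2a (−3.54, adjusted p 0.0113), Lipf (−5.70, adjusted p 0.0453) and Cux2 (−3.49, adjusted p 0.0453). Large rises were Olig1 (2 counts in controls, 109-fold higher with a counting interval of 29.6 to 905, adjusted p 0.00404), Mst1 (4.48, adjusted p 0.0299), S100b (3.64, adjusted p 0.00708), the kinase gene Wnk4 (3.32, adjusted p 0.0305), the lipoxygenase gene Alox15 (3.11, adjusted p 0.0417) and Plekhg6 (2.71, adjusted p 0.00432). S100b was again the 1 called gene of 10 in the neural and Schwann list, with 2 up adjusted over the list alone and all 10 members above 0 (median 0.83, adjusted p = 0.111 with an estimated correlation).

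Macrophage genes were higher in iWAT HFD KO, with Gpnmb called (1.07, adjusted p 0.023), 13 up adjusted over the list alone and a median of 0.69 (adjusted p = 0.426 with an estimated correlation). No lymphocyte gene of 19 was called, 3 fell adjusted over the list alone (median −1.97, adjusted p = 0.426 with an estimated correlation), and Ltb and Ccr7 had log2 fold changes of −3.23 (adjusted p 0.143) and −2.01 (adjusted p 0.141). Lymphocyte genes summed to 239 CPM in 1 control library and to 35.3 in the other, beside 43.1 and 35.8 in KO. After the receptor gene rate was subtracted, 90 of 92 higher and 88 of 103 lower genes were still called. Leaving out control replicate 1 or 2, or KO replicate 1 or 2, changed the count of 195 to 32, 19, 29 and 14, the block left 12, and DESeq2 called 1062 and the 4 libraries alone 2035. Olig1, Itgad and Dnajc6 of the 23 called genes named here stayed called whichever library was left out.

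The KO effect averaged over the 4 settings gave the sharpest view, since all 16 libraries enter it. The labels do not say whether eWAT and iWAT libraries come from the same mice, and the model treats all 16 as independent. Adipocyte identity genes fell, 10 of 25 and 12 adjusted over the list alone (1 rose), with a median of −0.32 (camera adjusted p 1.79e-12, but adjusted p = 0.242 with an estimated correlation). Retn fell by 1.43 (SE 0.15, adjusted p 2.38e-04), Adrb3 by 1.21 (adjusted p 7.3e-04) and Gpd1, which makes glycerol phosphate for triglycerides, by 0.88 (adjusted p 0.00198). Lipogenesis genes fell, 7 of 22 and 10 adjusted over the list alone (median −0.34, adjusted p = 0.242 with an estimated correlation), among them Slc25a1 (−1.47, adjusted p 1.46e-04), the lipid droplet gene Pnpla3 (−1.44, adjusted p 0.00104), Me1 (−1.09, adjusted p 1.46e-04) and Insig1 (−1.07, adjusted p 0.0026). Lipolysis and oxidation genes fell, 7 of 20 and 11 adjusted over the list alone (1 rose; median −0.31, adjusted p = 0.339 with an estimated correlation), with Decr1 at −1.08, Ehhadh at −1, Echs1 at −0.45 and Slc25a20 at −0.40.

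Macrophage genes rose on average, 10 of 25 and 14 adjusted over the list alone (median 0.36, adjusted p = 0.242 with an estimated correlation), with Gpnmb at 0.97 (adjusted p 1.41e-04), Ctss at 0.59, the lysozyme gene Lyz2 at 0.58 and Lgals3 at 0.56. This average joins settings that differed in direction. Of 22 immediate early genes 3 rose, 10 adjusted over the list alone (median 0.33, adjusted p = 0.242 with an estimated correlation), namely Atf3 (0.75), Nr4a1 (0.75) and Myc (0.45). The neural and Schwann list had 1 of 10 up, S100b, and 3 adjusted over the list alone (median 0.42, adjusted p = 0.0948 with an estimated correlation). The largest average rises were Olig1 (4.29, SE 0.36), S100b (3.86, SE 0.24), Chst8 (2.31, SE 0.19), Chchd10 (2.20, SE 0.18), Plekhg6 (2.13, SE 0.17) and the kininogen gene Kng2 (2.12, SE 0.32). The largest falls were Lipf (−5.65, SE 0.68), the glutamate receptor gene Grid1 (−3.44, SE 0.46), Kcne1l (−3.31, SE 0.39), Ifi27l2a (−3.21, SE 0.25), the major urinary protein gene Mup19 (−2.66, SE 0.59, adjusted p 0.0258) and Klf14 (−2.53, SE 0.23). Lipf measured 0 CPM in both iWAT chow KO libraries, so the size of its average fall is rough. Mup19 measured 79.8 CPM in iWAT chow control replicate 1 against 7.37 in replicate 2, and it was not called in some of the runs that left out 1 library. Mup genes share much sequence, so reads can be shared among them.

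In edgeR 1218 genes were called in the average, 513 up and 705 down. Among single libraries left out, those in eWAT on chow gave 666, 675, 751 and 698 genes (control, then KO), those in iWAT on HFD 694, 748, 708 and 734, iWAT chow KO replicate 2 gave 1849, and the other 7 stayed within 1.5 times. The block left 652 and DESeq2 called 2414, and the chow settings alone gave 339, with 208 up and 131 down, so the larger share of falls depends on the HFD libraries. Of 32 called genes named here 26 stayed called whichever library was left out.

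Across the settings, 8 genes were called the same way in all 4. This count rests on the 30 calls in iWAT on chow, which became 1 with a replicate block and 0 with the 4 libraries alone, while DESeq2 called 260. Chchd10, Chst8, Kcnc3 (a potassium channel), Pcolce (an enhancer of procollagen processing) and S100b rose, and Ifi27l2a, Pik3cb and Rasgrf2 fell. Pik3cb had log2 fold changes of −0.83, −1.07, −0.94 and −1.53 in eWAT and iWAT on chow and eWAT and iWAT on HFD, and Pcolce had 1.10, 1.36, 1.04 and 2.31. Pairs of settings shared more calls than independent lists would. eWAT and iWAT on HFD shared 27 genes up (0.565 expected) and 48 down (1.17 expected), and the chow pair shared 7 up (0.0802 expected) and 6 down (0.0199 expected). eWAT on chow and on HFD shared 9 up and 7 down, while 35 genes were called in opposite directions (1.75 expected).

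**Figure D3:**
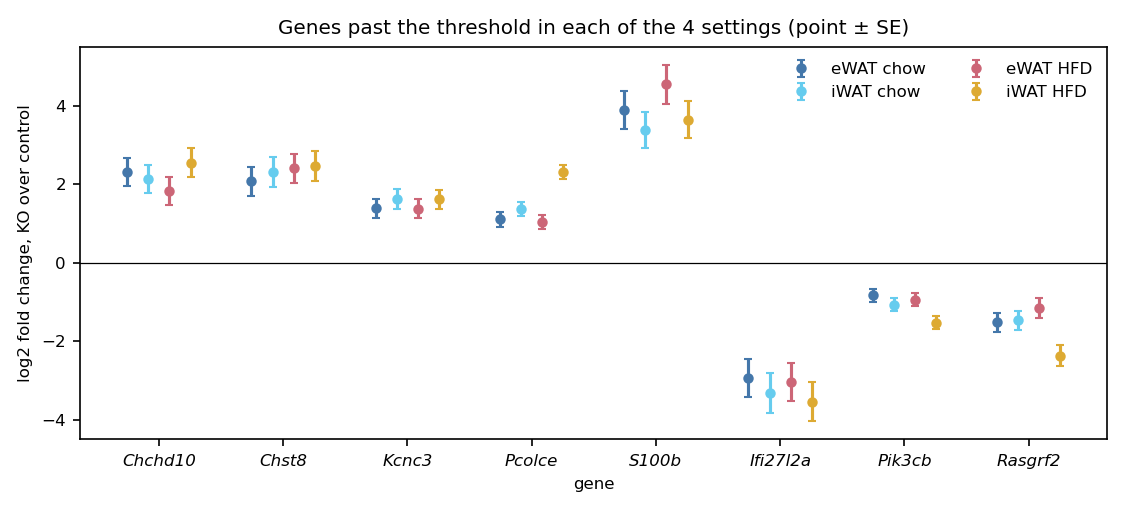
Log2 fold change of KO over control for the 8 genes called in all 4 depot and diet settings. Points are estimates and bars are SE. S100b lies between 3.38 and 4.54 and Ifi27l2a between −3.54 and −2.94.

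Whether the KO effect depended on diet was tested as a difference of differences. In eWAT macrophage genes had a more negative KO effect on HFD than on chow, 13 of 25 called and 20 adjusted over the list alone (1 the other way), with a median difference of −2.33 (camera adjusted p 7.94e-57, and adjusted p = 0.0135 with an estimated correlation). Gpnmb differed by −5.96 (SE 0.28, adjusted p 1.17e-06), Lgals3 by −3.27, Cd68 by −3.24 and Ctss by −2.78. Cell cycle genes had 2 of 24 called, 9 adjusted over the list alone (median −1.33, adjusted p = 0.0621 with an estimated correlation), and matrix genes 2 of 24, 12 adjusted over the list alone (median −0.91, adjusted p = 0.182 with an estimated correlation). Hira (0.14, adjusted p 0.904) and Adipoq (0.27, adjusted p 0.831) did not pass. In all 254 genes were called, 29 with a higher and 225 with a lower KO effect on HFD. Leaving out chow control replicate 1 or 2, chow KO replicate 2, HFD control replicate 1, HFD KO replicate 1 or HFD KO replicate 2 gave 65, 114, 108, 117, 146 and 655 genes, the block left 74, DESeq2 called 828 (258 higher, 570 lower), and the 8 libraries alone 62 (1 higher, 61 lower). Of 19 called genes named for this difference 7 stayed called whichever library was left out, namely Itgad, Gpnmb, Atp6v0d2, Otop1, Lgals3, Cd68 and Ctss. Diet went with age here (23 weeks on chow, 16 weeks on HFD), and both eWAT HFD KO libraries had more mesothelial RNA than the controls on HFD, while only KO replicate 1 stood out in epididymal RNA.

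**Figure D4:**
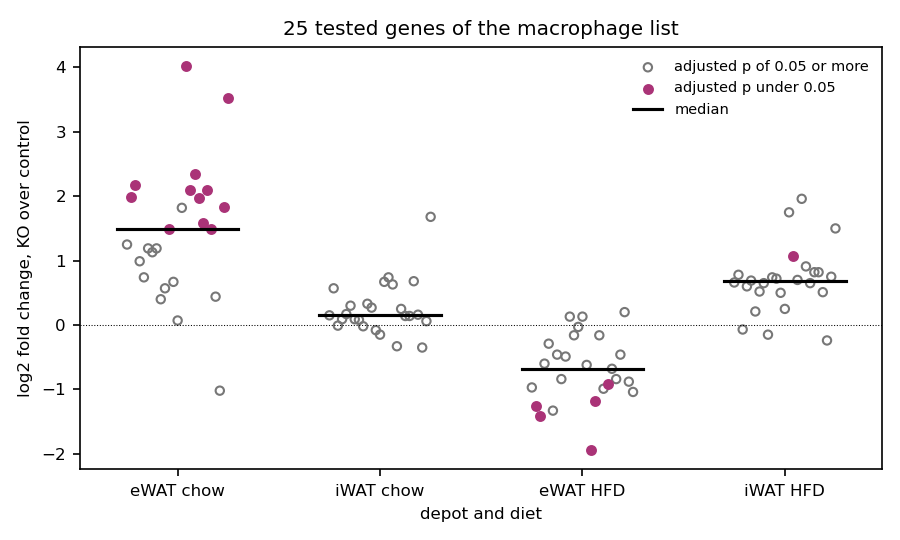
Log2 fold change of KO over control for the 25 tested genes of the macrophage list in each depot and diet. Filled points were called, open points were not, and bars are medians, which stand at 1.49 in eWAT on chow and −0.68 in eWAT on HFD.

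In iWAT 2 genes had a KO effect that differed by diet, Itgad (−4.31, SE 0.50, adjusted p 0.0171) and Dnajc6 (−3.60, SE 0.36, adjusted p 0.00605). Both were lower in KO on HFD. The neural and Schwann list passed, with no member called over all genes or adjusted over the list alone, all 10 members above 0 and a median of 1 (adjusted p = 0.0404 with an estimated correlation). Pmp22 had 0.85 and Plp1 1.63, both myelin genes and both with adjusted p of 0.951 or more. The lymphocyte list (median −2.09), mammary list (4.38) and macrophage list (0.44) had adjusted p = 0.598, 0.129 and 0.598 with an estimated correlation and no member called either way. Single control libraries stood apart here. Mammary genes summed to 117 CPM in 1 chow control library and 12.6 in the other, and lymphocyte genes to 239 in 1 HFD control library and 35.3 in the other. Hira (−0.71, adjusted p 0.967) and Adipoq (−0.22, adjusted p 1) did not pass. Leaving out single libraries gave 0 to 6 genes (6 without chow control replicate 2, 0 without chow control replicate 1, HFD control replicate 1 or either HFD KO library, and 1 without either chow KO library), the block left 0 and the 8 libraries alone 1, while DESeq2 called 56.

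Whether the KO effect depended on the depot was tested in the same way. On chow Gpnmb (−3.27, SE 0.26, adjusted p 6.58e-04) and Slc37a2, a sugar phosphate transporter of macrophages (−2.46, SE 0.27, adjusted p 0.00834), had a lower KO effect in iWAT than in eWAT. Of 25 macrophage genes 1 was called, 12 adjusted over the list alone, with a median of −1.11 (adjusted p = 0.0174 with an estimated correlation). On HFD the sign was the opposite. Gpnmb (3.01, adjusted p 0.00156), the metalloprotease gene Adam8 (2.74, adjusted p 0.0223) and the hexokinase gene Hk3 (2.51, adjusted p 0.0142) had a higher KO effect in iWAT, 4 of 25 macrophage genes were called, and 19 were called adjusted over the list alone (median 1.51, adjusted p = 0.0605 with an estimated correlation). Dnajc6 was the 1 gene of 26 with a lower KO effect in iWAT on HFD (−2.15, adjusted p 0.0394). Adipoq did not pass on chow (−0.20, adjusted p 1) or HFD (−0.69, adjusted p 0.77), nor did Hira (0.41, adjusted p 1, and −0.44, adjusted p 0.834).

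For the depot test on chow, the count of 2 became 1 without either eWAT control library, eWAT KO replicate 1, iWAT control replicate 1 or iWAT KO replicate 1, and 4 without iWAT control replicate 2. RLE scaling also gave 4, the block 0, the 8 libraries alone 1 and DESeq2 68. For the depot test on HFD, the count of 26 became 1 without eWAT control replicate 1, eWAT KO replicate 1, either iWAT control library or iWAT KO replicate 1, 3 without iWAT KO replicate 2 and 95 without eWAT KO replicate 2. The block gave 0, the 8 libraries alone 0, no filter 7 and DESeq2 229.

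Control mice showed what differed between HFD and chow, together with age. In eWAT macrophage genes rose, 18 of 25 and 20 adjusted over the list alone (1 fell), with a median of 2 (camera adjusted p 9.8e-32, but adjusted p = 0.0514 with an estimated correlation). Gpnmb rose from 30.4 ± 1.95 to 814 ± 148 CPM (4.75, SE 0.21, adjusted p 7.62e-07), Lgals3 by 3.4, and Tyrobp and Ctss each by 2.56. Cell cycle genes rose, 18 of 24 and 22 adjusted over the list alone (median 1.51, adjusted p = 0.0514 with an estimated correlation), among them Tk1 (2.50), Cdk1 (2.30), Top2a (2.30) and Mcm5 (1.55). Matrix genes rose, 10 of 24 and 13 adjusted over the list alone (1 fell; median 0.66, adjusted p = 0.42 with an estimated correlation), with Timp1 at 2.94 and Sparc, from 3090 ± 510 to 8220 ± 1940 CPM, at 1.41. Lox (1.09) and Col6a2 (1.32) rose with them.

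Endothelial genes fell in eWAT on HFD, 10 of 14 by either adjustment, with 10 adjusted over the list alone (median −0.90, adjusted p = 0.257 with an estimated correlation), among them the receptor genes Kdr (−1.57) and Flt1 (−1.25), Robo4 (−1.22) and Esam (−0.88). Circadian genes fell, 5 of 18 and 8 adjusted over the list alone (median −1.12, adjusted p = 0.257 with an estimated correlation), such as Rorc (−2.16), Bhlhe40 (−1.68), Nr1d1 (−1.52) and Cry2 (−0.65), and the time of day of collection was not among the labels used. Adipogenic transcription factors fell, 5 of 19 and 10 adjusted over the list alone (median −0.65, adjusted p = 0.42 with an estimated correlation), with Ebf2 (−1.33), Klf15 (−1.11), Pparg (−1.06) and Nr2f2 (−1.02). The largest falls were Cyp2f2 (−4.17), the ciliary genes Dnahc5 (−3.94) and Rsph4a (−3.84), Acsm3 (−3.64), Tmem88b (−3.39) and the noncoding RNA gene Snhg11 (−3.28). Some of the genes that rose had no reads in either chow control library and varied between the HFD libraries. Against a floor of 3 counts over the group, Morc2b was at least 468-fold higher, Fam186b 247-fold, Zswim2 210-fold, Prss46 201-fold, Dsg1a 189-fold and Dazl 153-fold, with SD above the mean for all but Dsg1a. Apart from Dsg1a these bounds rest mostly on HFD control replicate 2. Morc2b measured 33.2 CPM there against 1.45 in replicate 1, Fam186b 17.5 against 0.771, Zswim2 15 against 0.53, Prss46 13.7 against 1.45 and Dazl 10.9 against 0.289. In eWAT HFD KO replicate 1 the same genes measured 11, 6.85, 6.02, 5.68 and 2.06 CPM, each above replicate 2. They thus moved together in single libraries, and RNA of another tissue was not tested as their source.

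In edgeR 2200 genes were called in eWAT controls, 1197 up and 1003 down. Leaving out chow replicate 1 or 2, or HFD replicate 2, gave 452, 784 and 1140 genes, and without HFD replicate 1 there were 1257 up but 438 down. The alternatives gave 1231 (block), 673 (the 4 libraries alone) and 4060 (DESeq2), and 16 of 36 called genes named for these controls stayed called whichever library was left out. Hira (−0.14, adjusted p 0.623) and Adipoq (−0.53, adjusted p 0.147) did not pass. Of the 145 genes up in eWAT KO on chow, 129 were also up on HFD in controls (9.6 expected). Both contrasts share the chow controls, which the expected number leaves out. With 1 chow control library for KO and the other for the diet, chosen after the data were seen, 24 of 28 genes up in KO were also up on HFD (0.403 expected), and 16 of 18 in the reverse arrangement (0.424 expected), so shared controls do not account for that part. Over all genes the correlation was 0.01, where simulated groups with shared controls and no change gave 0.49. With the separate control libraries it was −0.08 and −0.16, so the overlap of called genes does not extend to all genes.

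In iWAT controls Lep, the leptin gene, rose from 829 ± 31.6 to 5990 ± 194 CPM on HFD (2.85, SE 0.23, adjusted p 1.04e-04), and Adipoq rose from 1680 ± 115 to 3510 ± 93.8 CPM (1.06, SE 0.24, adjusted p 0.0099). Hira did not pass (0.03, adjusted p 0.968). Of 25 adipocyte identity genes 8 rose and 2 fell, 13 and 2 adjusted over the list alone (median 0.69, adjusted p = 0.607 with an estimated correlation), with Cidec (1.46) and the glycerol channel gene Aqp7 (1.35) up and Adrb3 (−2.04) down. Lipolysis and oxidation genes rose, 7 of 20 with 1 down, 11 and 1 adjusted over the list alone (median 0.58, adjusted p = 0.607 with an estimated correlation), with Mgll (1.43), Slc25a20 (0.97), Decr1 (0.93) and Cpt1a (0.87). Matrix genes rose, 10 of 24 and 12 adjusted over the list alone (median 0.52, adjusted p = 0.607 with an estimated correlation), with the thrombospondin gene Thbs1 (3.78), Sparc (2.01), Acta2 (1.99) and Lox (1.60).

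Lymphocyte genes fell in iWAT on HFD, 12 of 19 and 18 adjusted over the list alone (median −2.96, adjusted p = 0.384 with an estimated correlation), with Ccr7 (−3.49), Sell (−3.41), Il7r (−2.96) and Cd4 (−2.96). Summed lymphocyte genes measured 711 to 1040 CPM in chow controls and 35.3 and 239 CPM in HFD controls. In iWAT KO they measured 899 to 1120 CPM on chow and 35.8 to 43.1 on HFD. Such levels cannot tell a change within fat from a different amount of lymphoid tissue in the samples. Sidt1, Fam169b, Ccr6 and Ipcef1, named below, also measured more in each iWAT chow library than in any iWAT HFD library. Endothelial genes fell, 9 of 14 and 11 adjusted over the list alone (median −0.87, adjusted p = 0.607 with an estimated correlation), with Kdr (−1.69), Flt1 (−1.44), Tie1 (−1.04) and Vwf (−0.97). Neural and Schwann genes had 4 of 10 down and 1 up, 7 and 1 adjusted over the list alone (median −1.96, adjusted p = 0.206 with an estimated correlation), with the myelin genes Plp1 (−2.63), Mpz (−2.21), Prx (−1.89) and Mbp (−1.55) down. The largest rises were Itgad (7.02, adjusted p 2.9e-06), Tph2 (6.03), Lipf (5.64), the oxytocin receptor gene Oxtr (5.57), Tmem132b (5.28) and Pramef12 (5.20). Large falls were Fcgbp (2 counts on HFD, 163-fold lower with a counting interval of 45 to 1350, but 16.1 CPM in chow replicate 1 against 1.18 in chow replicate 2, without the first of which it was not called, at −4.28), Tmem150c (−5.26), Sidt1 (−4.33), Fam169b (−4.29), the chemokine receptor gene Ccr6 (−4.28) and Ipcef1 (−4.21). In edgeR 3298 genes were called, 1554 up and 1744 down. Leaving out chow replicate 1 or 2, or HFD replicate 1 or 2, gave 1269, 1745, 1017 and 1559 genes, and 21 of 37 called genes named for these controls stayed called in every such run. The depots shared 401 genes up (103 expected) and 417 down (96.8 expected), with 104 in opposite directions (202 expected).

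In 3T3-L1 cells the comparison of day 4 with day 0 described differentiation. All 24 tested adipocyte identity genes rose, also 24 adjusted over the list alone, with a median of 6.2 (camera adjusted p 1.76e-50, but adjusted p = 0.0874 with an estimated correlation). Adipoq rose from 0.191 ± 0.0645 to 1450 ± 12.5 CPM (12.89, SE 0.07, adjusted p 1.26e-27), and Cidec (13.46), Plin1 (9.55) and Gpd1 (9.46) rose with it. Lipogenesis genes rose, 20 of 22 with 2 down and the same numbers adjusted over the list alone (median 1.86, adjusted p = 0.141 with an estimated correlation), among them Dgat2 (7.79), Scd1 (5.30), Lpin1 (4.36) and Dgat1 (4.06). Lipolysis and oxidation genes had 17 of 20 up and 3 down by either adjustment, with 17 and 3 adjusted over the list alone (median 1.77, adjusted p = 0.141 with an estimated correlation), with Lipe (6.20), Pnpla2 (5.11) and Abhd5 (2.12) up and Cpt1a (−4.42) down. Glucocorticoid response genes had 13 of 14 up and 1 down, the same adjusted over the list alone (median 2.19, adjusted p = 0.141 with an estimated correlation), with Lcn2 (8.34), Errfi1 (3.74), Fkbp5 (3.72) and Mt2 (3.13), and the induction medium held dexamethasone per the labels.

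Interferon response genes fell on day 4, 21 of 22 with 1 up by either adjustment, 21 and 1 adjusted over the list alone (median −4.69, adjusted p = 0.141 with an estimated correlation), among them Ifit3 (−7.81), Oasl2 (−7.76), Ifit1 (−7.56) and Bst2 (−4.72). Matrix genes fell, 21 of 24 with 3 up, the same adjusted over the list alone (median −2.01, adjusted p = 0.141 with an estimated correlation), with Acta2 (−6.17), Thbs1 (−5.51), Postn (−3.40) and Mmp14 (−3.33). Other large falls were the melanocyte gene Mlana (−8.81), Rsad2 (−8.54), Ces1a (−8.43), Oas2 (−8.15) and Ifi44 (−7.89). Cfd, the adipsin gene, and Retn had 2 counts each on day 0 and rose 101000-fold (counting interval 27900 to 831000) and 25000-fold (6910 to 206000). Mrap, Ghrh, O3far1 and Ffar2 had no reads on day 0 and were at least 6180-fold, 2290-fold, 1730-fold and 1680-fold higher against a floor of 3 counts over the group. Hira fell slightly, from 59.6 ± 0.247 to 53.6 ± 1.19 CPM (−0.15, SE 0.04, adjusted p 8.66e-04). In all 12177 of 14373 genes were called, 6134 up and 6043 down, and all 36 called genes named here stayed called whichever library was left out.

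The EU-RNA comparisons asked how loss of the HIRA protein changed new transcription in day 4 cells within hours. At 3 h no gene was called by edgeR, 250 of 17868 genes had an unadjusted p under 0.05, and DESeq2 called 1. The smallest p among immediate early genes belonged to Fosb (−1.36, SE 0.23, adjusted p 1) and Fos (−0.48, adjusted p 1), and 2 genes of that list were lower adjusted over the list alone (median −0.10, adjusted p = 0.617 with an estimated correlation). Among lipogenesis genes Acss2 (0.39) and Insig1 (0.38) had the smallest p, and 2 were higher adjusted over the list alone (median 0.05, adjusted p = 0.617 with an estimated correlation). Adipocyte identity genes lay under 0 in 24 of 25 cases with none called either way (median −0.16, adjusted p = 0.617 with an estimated correlation), with Pck1 at −0.58, Cidec at −0.25 and Adipoq at −0.23. Interferon genes Mx2 (0.38) and Cxcl10 (0.46), histone genes Hist1h1a (0.31) and Hist2h4 (0.32), and adipogenic factors Nr1h3 (−0.21) and Ebf2 (−0.16) were not called (adjusted p 1), and their lists had adjusted p = 0.617, 0.775 and 0.617 with an estimated correlation. Leaving out 3 h replicate 2 gave 1 gene, as did the 4 libraries alone. In simulated data with this spread, 79.1% of genes changed 2-fold were called, so most changes of that size in a limited set of genes were detectable. The simulated changes were confined to a small part of the genes. A shift shared by most genes was not simulated, and TMM scaling could absorb it, since levels are relative to the other genes. The absence of calls thus does not bear on such a shift.

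At 6 h no gene was called by edgeR either, 1557 had an unadjusted p under 0.05, DESeq2 called 5, no filter 2, and leaving out 6 h replicate 1 gave 171. Immediate early genes lay above 0 in 21 of 22 cases, with 12 up and 1 down adjusted over the list alone (median 0.38, adjusted p = 0.728 with an estimated correlation), such as Atf3 (0.51, adjusted p 0.525) and Cyr61 (0.44, adjusted p 0.525). Replication-dependent histone genes lay above 0 in 19 of 19 cases with none called either way (median 0.39, adjusted p = 0.728 with an estimated correlation), such as the linker histone genes Hist1h1c (0.37) and Hist1h1e (0.27). Adipoq measured 40.6 ± 5.37 CPM against 57.1 ± 5.64 with DMSO (−0.49, SE 0.12, adjusted p 0.525) and Cidec had −0.39, and 2 adipocyte identity genes were lower adjusted over the list alone (median −0.10, adjusted p = 0.728 with an estimated correlation). Cpt2 (−0.29), Acadm (−0.21), Plk1 (−0.35), Bub1b (−0.18), Mmp2 (−0.37) and Thbs1 (0.39), named from further lists that passed camera at the preset correlation, were not called. None of the 8 lists that passed at 6 h did so with an estimated correlation (smallest adjusted p = 0.728).

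At 24 h 204 genes were called, 110 up and 94 down. Replication-dependent histone genes rose, 3 of 19 over all genes and 18 adjusted over the list alone, with all 19 above 0 and a median of 1.08 (camera adjusted p 2.78e-36, but adjusted p = 0.182 with an estimated correlation). Hist1h1c went from 73.3 ± 6.95 to 153 ± 30.6 CPM (1.06, SE 0.13, adjusted p 0.00318), with Hist1h1e (0.97) and Hist1h1a (0.93). Hist1h2bf, Hist1h2bh, Hist1h2bn and Hist1h2ak rose by 1.28, 1.26, 1.23 and 1.21. Immediate early genes rose, 15 of 22 and 19 adjusted over the list alone (median 0.60, adjusted p = 0.103 with an estimated correlation), such as Ier3 (1.11), Klf6 (0.74), Egr1 (0.61) and Jun (0.56). The matrix genes Ctgf (1.96, adjusted p 0.0249), Acta2 (1.04) and Thbs1 (0.76) were 3 of 23 on their list, 5 up and 1 down adjusted over the list alone (median 0.18, adjusted p = 0.36 with an estimated correlation), and Ankrd1, like Ctgf a known target of YAP, rose by 1.55 (adjusted p 0.00318).

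Lipogenesis genes fell at 24 h, 7 of 22 and 13 adjusted over the list alone (median −0.37, adjusted p = 0.103 with an estimated correlation). Acaca, acetyl-CoA carboxylase, went from 559 ± 17.7 to 402 ± 6.9 CPM (−0.47, SE 0.07, adjusted p 0.00855), with Acly (−0.49), Dgat1 (−0.52), Pnpla3 (−0.52) and, outside the list, the glucokinase gene Gck (−0.83, adjusted p 0.00318). Adipocyte identity genes fell, 3 of 25 and 13 adjusted over the list alone (median −0.32, adjusted p = 0.274 with an estimated correlation), namely Retn (−0.73), Adig (−0.70) and Plin1 (−0.65). Adipoq measured 41.2 ± 1.34 CPM and did not pass (−0.47, SE 0.12, adjusted p 0.072). Of 20 lipolysis and oxidation genes Mgll fell (−0.53), 8 adjusted over the list alone (median −0.19, adjusted p = 0.362 with an estimated correlation). Other falls were Rdh12 (−1.08), Fam107a (−0.96), Sh2d7 (−0.92), Mmd2 (−0.88) and Mtap7d2 (−0.85). Hira RNA, from the locus already disrupted in these cells, had log2 fold changes of 0.04, 0.01 and 0.02 at 3, 6 and 24 h, none called.

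The lists of genes induced and repressed on day 4 come from mRNA libraries without reads of the Y-linked gene Ddx3y (0 CPM in all 4), while the EU-RNA libraries held 34.9 to 50.7 CPM, so the 2 sets of 3T3-L1 cells differ in more than HIRA and the assay. The 200 genes most induced on day 4 were lower in EU-RNA at 24 h, with 30 of 198 called down and 1 up, 94 and 3 adjusted over the list alone (median −0.29, adjusted p = 0.0251 with an estimated correlation). The 200 most repressed were higher, 14 of 200 called, 46 up and 1 down adjusted over the list alone (median 0.20, adjusted p = 0.0736 with an estimated correlation). In the average KO effect in tissue, 37 of 199 induced genes were down and 7 up, 61 and 25 adjusted over the list alone (median −0.17, adjusted p = 0.102 with an estimated correlation). The average KO effect and EU-RNA at 24 h shared 15 genes up (3.13 expected) and 20 down (3.89 expected), with 6 in opposite directions (7.18 expected). The average KO effect and day 4 shared fewer calls than expected, 162 up (189 expected) and 138 down (265 expected), while 679 were in opposite directions (455 expected). All 3 times share the DMSO libraries, and simulated unchanged groups gave a correlation across genes of 0.50 against 0.45 to 0.51 observed. The covariances for 3 h and 6 h, 3 h and 24 h, and 6 h and 24 h were 0.0574, 0.0543 and 0.0729, above the simulated 0.0459, 0.0455 and 0.0453, and 68.3, 65.4 and 70.6% of genes had the same sign against 66.7, 66.7 and 66.9% simulated. The shared control alone thus gives a correlation of this size, and the excess in covariance was not tested.

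Leaving out DMSO replicate 1 or 2, or 24 h replicate 1 or 2, changed the 24 h count of 204 to 85, 0, 1866 and 29. No filter gave 440, the 4 libraries alone 58 and DESeq2 795, and none of the 29 called genes named here stayed called whichever library was left out. Against 3 h in place of DMSO, 73 genes were higher and 16 lower at 24 h. Of 22 immediate early genes 15 were higher, 20 adjusted over the list alone (median 0.73, adjusted p = 0.0375 with an estimated correlation), with Fos at 1.16 (SE 0.13, adjusted p 0.00143), Egr1 at 0.72 and Jun at 0.70. Of 22 lipogenesis genes 5 were lower, 16 adjusted over the list alone (median −0.34, adjusted p = 0.0375 with an estimated correlation), with Acly at −0.64 (SE 0.07, adjusted p 0.00143). Histone genes had 2 of 19 higher, 14 adjusted over the list alone (median 0.90, adjusted p = 0.172 with an estimated correlation). Leaving out 3 h replicate 1 or 2, or 24 h replicate 1 or 2, changed the count of 89 to 17, 5, 1228 and 35, no filter gave 182 and DESeq2 384. Dusp6 and Fos of the 20 called genes named for this contrast stayed called whichever library was left out.

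**Figure D5:**
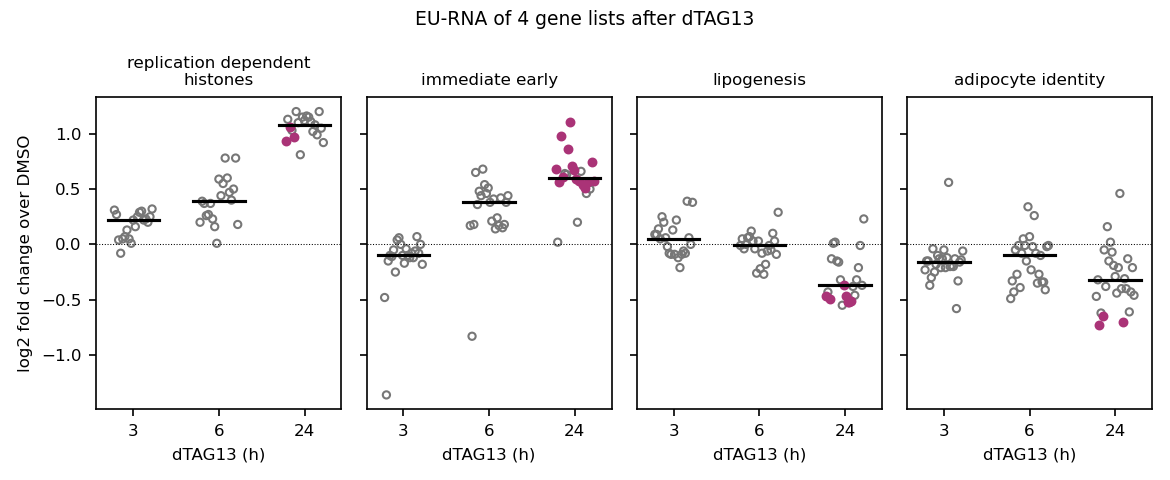
Log2 fold change of EU-RNA over DMSO for each tested gene of 4 fixed lists at 3, 6 and 24 h of dTAG13. Filled points were called by edgeR, open points were not, and bars are medians. The histone median stands at 0.22, 0.39 and 1.08 and the lipogenesis median at 0.05, −0.01 and −0.37.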

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

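The tests of dilution, background and exchanged labels in this part were chosen after the results were seen. The differences themselves come from planned interaction tests, which asked whether the effect of KO, or of time, differed between groups.

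In eWAT the KO effect differed between HFD and chow for 254 genes. It was lower on HFD for Itgad (−6.67), Tph2 (−6.08), Gpnmb (−5.96), Atp6v0d2 (−4.99), Otop1 (−4.97), Gdf3 (−4.72), Lgals3 (−3.27), Cd68 (−3.24), Ctss (−2.78), Tk1 (−2.27), Mki67 (−2.03), Lox (−1.79) and Postn (−1.47). It was higher on HFD for Gpr64 (3.15), Gsta4 (2.79), Mapt (2.74), Hddc3 (2.65), Cfd (2.36) and Krt19 (2.28), none of which stayed called whichever library was left out. The macrophage list had a median difference of −2.33. Krt19 is known from mesothelium and Gpr64 from the epididymis, and summed epididymal genes reached 9470 CPM in 1 eWAT HFD KO library. Gpr64 did not follow the epididymal genes across libraries, though. It measured 154 CPM in eWAT chow control replicate 1, where they summed to 7.05. In eWAT HFD control replicate 2 it measured 22.3 CPM, where they summed to 1140.

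Macrophage genes moved with genotype in opposite directions in eWAT on chow and on HFD. Their summed levels were 2150 and 2210 CPM in chow controls, 5520 and 5220 in chow KO, 7700 and 5590 in HFD controls and 3680 and 4520 in HFD KO. With an estimated correlation camera passed the macrophage list on chow and for the difference between diets. It passed no list for KO in eWAT on HFD (smallest adjusted p = 0.0832), so the fall on HFD by itself is less certain. Dilution of adipose RNA by another tissue would lower adipocyte genes alike, but their median difference was 0.22 (quartiles −0.33 to 0.65) against −2.33 for macrophage genes (quartiles −2.78 to −1.03). A uniform background at the rate of the silent receptor genes was too small to give the pattern, since the macrophage median was −2.33 with that rate subtracted. That rate rests on 1471 and 915 reads over 1450 genes in the eWAT HFD KO libraries, so the subtraction could change this list little. Other kinds of background were not tested by it. Exchanged genotype labels are argued against by 88.7% of genes called in iWAT on HFD having the same direction in eWAT on HFD. A change in the number or state of macrophages that depends on diet remains a candidate explanation, as a hypothesis found and tested on the same data. Age, which differed with diet, stays open and was not tested. A difference in processing between chow and HFD tables would act on both genotypes, so KO against control within a diet does not bear on it. A difference between HFD KO and HFD control libraries is another matter and stays open. In eWAT their share of reads in exons was 68.0 to 77.2% of the highest library in HFD KO and 89.9 to 90.4% in HFD controls. In iWAT macrophage genes summed to 3500 and 3620 CPM in HFD KO, above the 2350 and 2500 in HFD controls, so the fall was not seen in that depot.

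Genes higher in HFD KO libraries form the other pattern weighed here, because those 4 libraries also had the highest rate of reads in silent receptor genes. With that rate subtracted, 96.4% of the genes higher in eWAT and 97.8% of those higher in iWAT were still called higher. A uniform background at that rate thus does not account for these calls. The rate rests on 915 to 2546 reads over 1450 genes in each of these libraries, so it could remove few calls. The lower share of reads in exons of these libraries was not addressed by it and stays open. The subtraction assumes a background that grows with exon length. RNA of other tissues, which brings its own abundant genes, stays open for single genes, and no biological explanation was tested.

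In iWAT the KO effect differed between HFD and chow for 2 genes, Itgad (−4.31) and Dnajc6 (−3.60), and the neural and Schwann list had a median difference of 1. Between depots the KO effect differed on chow for 2 genes, Gpnmb (−3.27) and Slc37a2 (−2.46), and the macrophage list had a median difference of −1.11. Between depots on HFD it differed for 26 genes, among them Gpnmb (3.01), Adam8 (2.74), Hpgds (2.62), Hk3 (2.51), Timp1 (2.32), Myo1f (2.08), Cd68 (2.03), Lgals3 (1.88), Tyrobp (1.56) and Dnajc6 (−2.15).

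In EU-RNA the level differed between 24 h and 3 h of dTAG13 for 89 genes. It was higher at 24 h for Ctgf (1.90), Ankrd1 (1.40), Fosb (1.37), Dusp6 (1.21), Fos (1.16), Junb (1.08), Acta2 (1.08), Hist1h1c (1.01), Hist1h1e (0.92), Thbs1 (0.91), Cyr61 (0.76), Egr1 (0.72) and Jun (0.70), and the immediate early list had a median of 0.73. It was lower at 24 h for Mtap7d2 (−0.75), Pnpla3 (−0.74), Gck (−0.73), B4galnt2 (−0.70), Acly (−0.64), Acss2 (−0.59) and Acaca (−0.56), and the lipogenesis list had a median of −0.34.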

How the results depend on the processing

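The mean over transcripts, background subtraction, the models without the HFD KO or 6 h libraries, the crossed block and the separate chow controls were chosen after the data were seen, and the other alternatives were planned. Scaling mattered little. With RLE in place of TMM all counts of called genes stayed within 1.5 times except the depot test on chow, with 4 genes in place of 2. Of the named genes with RLE, 395 kept their direction and their side of the threshold, 2 were no longer called and 3 became called.

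DESeq2 called more genes in most comparisons. In KO against control it gave 612 in eWAT and 260 in iWAT on chow, 1472 in eWAT and 1062 in iWAT on HFD, and 2414 for the average. For the differences it gave 828 (diet in eWAT), 56 (diet in iWAT), 68 (depots on chow) and 229 (depots on HFD), for the diet in eWAT controls 4060, and in EU-RNA 1 at 3 h, 5 at 6 h, 795 at 24 h and 384 for 24 h against 3 h. Of the named genes 370 kept their side and 30 became called with DESeq2. The cause was not tested.

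A replicate block, which treats same-numbered libraries as paired, left 13 genes in eWAT and 1 in iWAT on chow, 1 in eWAT and 12 in iWAT on HFD, 652 for the average, 74 for the diet difference in eWAT, 0 for that in iWAT, 0 for the depots on chow, 0 on HFD and 1231 for the diet in eWAT controls. It costs residual degrees of freedom. The labels do not say that the numbers pair the libraries, and the deviations of same-numbered libraries had correlations across genes of −0.11 in eWAT and 0.33 in iWAT on chow and of −0.73 in eWAT and 0.08 in iWAT on HFD. A block with crossed numbers gave 388 genes in eWAT on chow and 968 in eWAT on HFD. Of the named genes 278 kept their side with the planned block and 122 were no longer called.

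Models with only the libraries compared have fewer samples to estimate the spread. They gave 521 genes in eWAT and 0 in iWAT on chow, 0 in eWAT and 2035 in iWAT on HFD, 62 for the diet difference in eWAT, 1 for that in iWAT, 1 for the depots on chow, 0 on HFD, 673 for the diet in eWAT controls, and 1 at 3 h and 58 at 24 h in EU-RNA. The counts of 0 stand beside planned models with more libraries and beside DESeq2 as given above. Replicates agreed unequally, with correlations of log2 CPM across genes of 0.9105 (KO) and 0.9323 (control) in eWAT on HFD. In iWAT on HFD these were 0.9839 and 0.9878. A spread pooled over the groups may thus be too small for eWAT on HFD and too large for iWAT on HFD. With no filter the counts were 18 in iWAT on chow, 7 for the depots on HFD, 2 at 6 h, 440 at 24 h and 182 for 24 h against 3 h. Without the HFD KO libraries iWAT on chow gave 0, and the chow settings alone gave 339 for the average. Background subtraction gave 1 for the diet difference in iWAT. The cause was not tested for these.

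Leaving out 1 library at a time, with the lone remaining sample assumed to vary like the other groups, gave 4 to 51 genes in eWAT and 0 to 384 in iWAT on chow, 36 to 1214 in eWAT and 14 to 32 in iWAT on HFD, and 666 to 1849 for the average. The ranges were 65 to 655 for the diet difference in eWAT, 0 to 6 for that in iWAT, 1 to 4 for the depots on chow, 1 to 95 on HFD, 452 to 1695 for the diet in eWAT controls, 1017 to 1745 in iWAT controls and 11342 to 12117 for day 4. In EU-RNA they were 0 to 1 at 3 h, 0 to 171 at 6 h, 0 to 1866 at 24 h and 5 to 1228 for 24 h against 3 h. Of the named gene results in these runs, 1685 kept their side, 571 were no longer called, 9 became called and 11 changed sign. The sign changes concerned small changes. Hira ranged from −0.54 to 0.01 in iWAT on chow, from −0.11 to 0.21 for the diet in iWAT controls, and in EU-RNA from −0.01 to 0.09 at 3 h, −0.07 to 0.08 at 6 h, −0.01 to 0.07 at 24 h and −0.07 to 0.04 for 24 h against 3 h. Adipoq ranged from −0.14 to 0.58 for the diet difference in eWAT and Hist2h4 from −0.20 to 0.69 at 3 h.

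The list tests depended most on the correlation between genes. Camera with the preset correlation, an estimated correlation and fry passed 13, 1 and 5 lists in eWAT on chow, 9, 0 and 0 in iWAT on chow, 13, 0 and 4 in eWAT on HFD, and 13, 0 and 1 in iWAT on HFD. They passed 8, 1 and 5 for the diet difference in eWAT, 11, 1 and 1 for that in iWAT, 5, 1 and 1 for the depots on chow, and 9, 0 and 1 on HFD. On day 4 they passed 12, 0 and 22, and in EU-RNA 7, 0 and 0 at 3 h, 8, 0 and 0 at 6 h, 11, 0 and 3 at 24 h, and 9, 2 and 2 for 24 h against 3 h. For the average and the diet in eWAT and iWAT controls an estimated correlation passed 0 in place of 12, 11 and 11. Of 30 tests of the day 4 lists, 21 passed, 1 did with an estimated correlation, and 20 and 23 did with lists of 100 and 500 genes.

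At an adjusted p under 0.1 the shared calls rose from 13 to 33 between eWAT and iWAT on chow, 16 to 34 between eWAT on chow and on HFD, 41 to 89 between eWAT on chow and iWAT on HFD, 11 to 23 between iWAT on chow and eWAT on HFD, 17 to 36 between iWAT on chow and on HFD, 75 to 178 between the depots on HFD, 35 to 117 between the average and EU-RNA at 24 h, 818 to 1441 between the diet effects, 139 to 219 between KO in eWAT on chow and the diet in eWAT controls (24 and 16 with a separate chow control library for each contrast, which leaves fewer samples), and 300 to 525 between the average and day 4, because more genes enter. At 0.05 the last pair shares 162 up and 138 down, fewer than the 189 and 265 expected by chance. How far depth limits each set was not tested. Tissue libraries held 11.4 to 34.3 M reads, against 77.2 M or more elsewhere, and also had the larger spread, with a biological coefficient of variation of 37.3% against 10.4% in EU-RNA and 2.83% in 3T3-L1 mRNA.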

Other observations

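The families and the test of genes next to Adipoq in adipose tissue were chosen after the results were seen, while the test of the same genes in EU-RNA and the splits of the libraries were set beforehand.

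Beside the genes already named, some families had several called members in the KO effect averaged over the 4 settings. The families themselves were not tested. All 3 genes of complement C1q, made mostly by macrophages, rose (0.46 to 0.50). Of 18 major urinary protein genes 10 fell (−3.06 to −2.22) and none rose, with Mup19 at 79.8 CPM in 1 iWAT chow control library and 7.37 in the other, and of 11 serpin A3 genes, which encode secreted protease inhibitors, 5 fell (−2.34 to −0.48). All 22 tested protocadherin gamma genes rose by nearly the same amount (0.45 to 0.49), but they share exons and so count the same reads. Urinary protein and serpin genes are close paralogs, so reads can be shared among them too. Of 11 S100a genes 2 rose (0.58 and 0.62). Cdc45, which lies near Hira in the genome, fell by 0.78 (SE 0.11, adjusted p 0.00159).

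RNA of tissues near the fat pads varied between libraries. Skeletal muscle genes summed to between 3830 and 38700 CPM in iWAT and to between 53 and 629 in eWAT. Lymphocyte genes summed to between 899 and 1120 CPM in iWAT chow KO.

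Kng2 was among the largest average rises in KO tissue and lies near Adipoq, whose regulatory region drives Cre. If copies of neighbouring genes were carried along with the transgene, genes next to Adipoq should be higher in KO. The 4 nearest tested genes on each side (Eif4a2, Snord2, Snora81, Rfc4, St6gal1, Masp1, Rtp4 and Bcl6) were higher in 8 of 8 cases in the average KO effect, with a median of 0.58, above 98.6% of such windows around other genes. Snord2 and Snora81 lie within Eif4a2 and do not count separately. By setting, the medians were 0.49, 0.26, 0.90 and 0.51 in eWAT and iWAT on chow and eWAT and iWAT on HFD, above 98.9, 90.7, 98.5 and 88.5% of windows, with 7, 6, 6 and 6 of the 8 genes higher, and Adipoq itself was lower. Of the 8, only Eif4a2 (0.58, adjusted p 0.00336) and Rfc4 (0.57, adjusted p 0.029) were called in the average, both on the side of Kng2. On the other side St6gal1 (0.63), Masp1 (1.11), Rtp4 (0.13) and Bcl6 (0.10) were not called. Copies carried with the transgene are a candidate explanation for the higher neighbours. Whether a carried stretch would reach Kng2, or both sides of Adipoq, stays open. Kng1, between Kng2 and Eif4a2, had negative changes in each setting (−0.52, −3.49, −0.30 and −2.27) and on average (−1.64, SE 0.65, adjusted p 0.166), Hrg averaged −2.31 (SE 1.19, adjusted p 0.292) and Fetub −0.42 (SE 0.50, adjusted p 0.721), none of them called, at low counts and with single control libraries apart (Kng1 measured 14.5 and 0.626 CPM in iWAT chow controls). An effect of HIRA loss on the region could not be excluded, since in EU-RNA at 24 h, from cells whose labels name no Cre, the median was 0.13, above 82.5% of windows.

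Of 80 splits of the libraries within depot and diet, drawn from 648 with the real one included, 1 called as many genes as the genotypes, which is the real one with 1218. The highest of the others called 1008 and differs from the real split by the exchange of 1 pair of libraries in iWAT on chow. No other split drawn reached the 1218 genes of the average KO effect, so a chance assignment of libraries is an unlikely origin of that count. The splits cannot separate genotype from the marks that the HFD KO libraries share.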
